A study of Mus musculus with 24 samples.

How the data were processed

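RNA was isolated from mouse colon with a magnetic bead kit, treated with DNase, checked on a Bioanalyser and converted to biotin-labelled cRNA for Illumina arrays, per the labels' protocols. Each of the 24 arrays was assigned to its group (wild-type vehicle, ApcMin vehicle, ApcMin naproxen, ApcMin ATB-346) from its label, and the replicate number was taken from the same label. The deposited gene table holds the average bead intensity of 18097 targets on a linear scale. It was made by the authors with GenomeStudio 1.7.0 without normalization, per the file headers, on MouseRef-8 v2.0 arrays. Whether a background was subtracted is not given in the sources used here. The intensities ran from 41.6 to 36652.2, and no detection p-values were used. A second deposited table, with the series matrix values, holds the intensity of 25697 probes, also on a linear scale, from GenomeStudio per the submitters' processing notes, with version and settings not given in the sources used here. For 9359 genes with 1 probe, 98.9% of its values lay within 0.05 intensity units of the gene table, so for these genes it is not an independent measurement. Its scale and direction are thus those of the gene table, and it served as an alternative. No column was without a sample.

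The gene table was the main source. Its intensities were background-corrected with limma's normexp method (offset 50), quantile-normalized between arrays and set to log2. The lowest normalized value was 5.65. Targets whose mean over the 24 arrays lay above the median mean (log2 6.54) were tested, 9048 of 18097. Of all targets, 14096 matched a current mouse gene symbol, 3025 matched through a synonym and 976 kept the file's name. Among tested targets 143 shared a symbol with another, and the one with the highest mean then stood for the gene. Of the probes, 23978 had 1 gene symbol, 1719 had none listed and 0 had several. Quantile normalization gives every array the same distribution, so a change in the total amount of RNA cannot be seen, and the offset draws changes of dim genes towards 0. Array medians before normalization were 81.4 to 92.7 in wild type, 86.6 to 96.1 in vehicle, 83.3 to 102.9 in naproxen and 82.4 to 99 in ATB-346 arrays. Arrays correlated with r between 0.928 and 0.994, and the smallest SD of the log2 difference between any pair was 0.177, so none was treated as a repeat of another. Xist was at most 6.20 and Ddx3y at least 8.35 on every array. The first principal component held 39.2% and the second 18.6% of the variance.

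One linear model with a mean per group was fitted to all 24 arrays (lmFit and eBayes, limma 3.58.1, R 4.3.3), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The contrasts were ApcMin vehicle against wild type, each drug against ApcMin vehicle, ATB-346 against naproxen, and each drug against wild type. Standard errors and 95% intervals come from this fit, and SDs are between the arrays of a group. The intervals of the probe-pair correlations between the cohorts are an exception and come from 1000 resamples of genes. The rule for named genes was: those with the largest rises and falls among called genes, or, with none called, the 5 with the smallest p in each direction, predicted genes excluded; the up to 4 members with the smallest p of each list described; and Apc, Ctnnb1, Myc, Ptgs1, Ptgs2, Cbs, Cth and Mpst always. Of the genes selected by this rule, 1 is not reported here.

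The 37 gene lists covered Wnt targets, prostanoids, hydrogen sulfide metabolism, Nrf2 targets, cell cycle, apoptosis, interferon and inflammatory genes, MHC class II, epithelial, stromal, immune, neural and other cell types of the gut and its surroundings, PPAR targets, xenobiotic metabolism, the circadian clock, immediate early genes, hypoxia, oxidative phosphorylation, the unfolded protein response and ribosomal proteins. Lists with at least 4 tested members, 33 in all, were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation (statmod 1.5.0), adjusted over 132 tests (33 lists in 4 contrasts). The other 4, posterior Hox genes (3 tested members), erythroid cells (3), mast cells (1) and neutrophils (0), were read by member only. Groups, contrasts, tests, lists and the rule for named genes were chosen before the data were examined.

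The fit was tested on simulated data: the arrays' residuals were dealt at random to the groups, 200 of 9048 genes were changed by log2 0.5, 1 or 2, and the share recovered over 10 runs was counted. Recovery at 2 was between 98.2% and 99.5% in the 6 contrasts, and at 1 between 89.1% and 94.9%. With 200 genes changed at once the adjusted cutoff is looser than with few. These shares therefore do not give the power to find a few changed genes. The false calls per run were 4 for the genotype, 13.6 for ATB-346 and 28.6 for naproxen against vehicle, 3.1 between the drugs, and 5.1 and 1.2 for ATB-346 and naproxen against wild type. A list moved by 0.5 was recovered in 10 of 10 runs in each of 4 contrasts. Each list run was adjusted over the 33 lists of 1 contrast, not over the 132 tests used for the real lists. These simulations of genes and lists did not keep the cohort. Correlations between contrasts that share the vehicle arrays were computed with those arrays split 4 and 4 (70 splits), beside 100 simulations of unchanged groups, 100 with the cohort shift kept (residuals of the cohort-blocked fit dealt within cohorts) and 100 from the first cohort alone. Single measures were compared with exact permutation tests and correlations across arrays with 100000 permutations, both in R. Figures and summaries of the alternatives were made in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).

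Samples that share a replicate number were checked for pairing by the correlation of their deviations from the group means. For wild-type and ApcMin vehicle arrays it was 0.118, 0.305, 0.375 and 0.673 for numbers 1 to 4, all above 0.1. These were treated as pairs in the replicate block and in the splits of same-numbered pairs, while the main fit and the exact tests were unpaired. Only 1 of the 4 correlated best with its own number, and the labels do not say what the number marks. The other groups had pairs at or below 0.1. A split of the arrays by replicate number (1 to 4 against 5 to 8) was found in the values, and the fit was repeated with this cohort as a block and within each cohort. Other alternatives were the series matrix values, no background correction, offset 16, median scaling, no filter or a stricter one, the mean of all probes of a gene, only the groups compared, array weights, a trended robust spread, a fold of at least 1.5, the replicate block, fry in place of camera, each array left out, and, added after the data were seen, the cohort with the Osr2 level or the acinar mean as a covariate, and the cohort block without vehicle replicates 1 and 2. Chromosome positions were not used here.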

Results

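Transcript levels were measured in total RNA from mouse colon on 24 single-colour Illumina bead arrays. The mice were C57Bl/6 controls or carried ApcMin, a point mutation in 1 copy of the tumour suppressor gene Apc that predisposes to intestinal tumours. From 6 weeks of age they received vehicle, naproxen or ATB-346 by daily gavage for 7 days, and colon was collected at 14 weeks of age, 7 weeks after the last dose. Naproxen, a cyclooxygenase-inhibiting NSAID, was given at 10 mg/kg, and ATB-346, the hydrogen sulfide-releasing NSAID of the study, at 14.5 mg/kg. The groups held 4 wild-type vehicle, 8 ApcMin vehicle, 6 ApcMin naproxen and 6 ApcMin ATB-346 arrays. The raw median signal of an array ranged from 81.4 to 102.9 intensity units, and the number of arrays limits the precision. The labels do not say that each array came from a separate animal, so p-values measure only the spread between these samples, part of which may be technical. All values are log2 normalized signals, given as mean ± SD, and differences carry their SE or 95% interval.

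Arrays numbered as replicates 5 to 8 (the second cohort: 4 vehicle, 2 naproxen and 2 ATB-346) were set against those numbered 1 to 4 (the first cohort, 4 per group) within their groups. Of 9048 tested genes, 3358 differed between the cohorts at a limma adjusted p under 0.05, 1328 higher and 2030 lower in the second. The shift was larger than 1 log2 unit in 136 of them. Ctnnb1, which encodes beta-catenin, lay at 11.42 ± 0.49 over all 8 vehicle arrays, with 10.88 to 11.05 in the first cohort and 11.68 to 12.03 in the second. All wild-type arrays belonged to the first cohort. Values with the cohort as a block and within each cohort therefore stand beside the results.

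**Figure D1:**
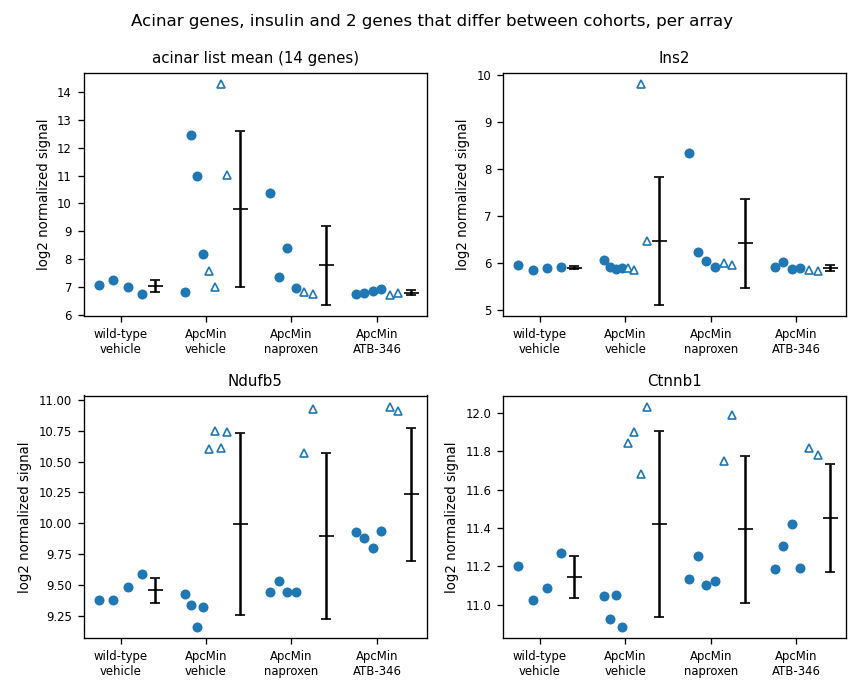
Log2 normalized signal (y axis) of the mean of 14 pancreatic acinar genes, of Ins2 and of Ndufb5 (both chosen after their values were seen) and of Ctnnb1 in the 24 arrays of the 4 groups (x axis). Filled circles are replicates 1 to 4, open triangles replicates 5 to 8, and the bar at the right of each group is its mean ± SD; the acinar mean reached 14.3 in vehicle replicate 7 and stayed between 6.72 and 6.94 in the ATB-346 arrays, while Ndufb5 and Ctnnb1 separated the cohorts.

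The first comparison asked how vehicle-treated ApcMin colon differed from wild-type colon. Genes for pancreatic digestive enzymes were higher in ApcMin: Pnlip (pancreatic lipase) lay at 10.06 ± 3.24 (SD, n = 8) against 6.31 ± 0.33 (n = 4), and Cela2a, an elastase, at 10.68 ± 3.40 against 6.72 ± 0.58. All 14 measured members of the acinar list were higher, by a median of 3.00, and 13 passed when adjusted over the list alone, against 0 over all genes. Retnlb, a goblet cell product, lay at 12.87 ± 2.10 against 9.69 ± 1.67, a difference of 3.18 (95% interval 0.79 to 5.57) that did not pass over the list alone (adjusted p = 0.114). Mzb1, a chaperone of antibody-secreting cells, was 0.76 ± 0.35 (SE) higher and stood above the wild-type mean in 8 of 8 arrays, but did not pass either (adjusted p = 0.157 over the list alone).

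In the genotype comparison, 5 of 33 gene lists passed limma's camera test with a preset correlation, all upward, and 0 passed with an estimated correlation. With the cohort as a block 6 passed. The goblet and colonocyte calls were lost, and 3 lists were gained, all upward: MHC class II (median 0.21, adjusted p = 0.00168), B cell (0.29, adjusted p = 0.00619) and immediate early and heat shock genes (0.15, adjusted p = 0.0176), each with an adjusted p of 0.804 with an estimated correlation. Within the first cohort the medians were 0.35 (adjusted p = 1.13e-07), 0.49 (0.000144) and 0.13 (0.0985). With the replicate number as a block the same 3 lists were called (medians 0.24, 0.31 and 0.14, adjusted p = 0.000934, 0.00374 and 0.0123), and adipocyte genes as lower (-0.63, adjusted p = 0.0404, against -0.43 and 0.262 without it), each with an adjusted p of 0.787 with an estimated correlation. Vehicle replicates 1 and 2 had B cell means of 8.26 and 8.12, against 6.71 to 7.27 in the other 6 vehicle arrays and 6.84 to 7.46 in wild type, and MHC class II means of 9.62 and 9.35, against 8.65 to 9.03 and 8.75 to 8.97. Only 4 of 8 vehicle arrays lay above the wild-type mean in either list. Under the cohort block the MHC class II call ended without vehicle replicate 1 (median 0.08, adjusted p = 0.225), the B cell call without replicate 1 (0.13, adjusted p = 0.225) or 2 (0.15, adjusted p = 0.122) and the immediate early call without replicate 2 (0.15, adjusted p = 0.0571). Without both replicates the MHC class II and B cell medians turned to -0.05 and -0.11 (adjusted p = 0.666 and 0.456), the adipocyte median was -0.10 (adjusted p = 0.931), and immediate early genes passed (0.15, adjusted p = 0.0410). Acinar genes had an adjusted p of 5.65e-15 (adjusted p = 0.374 with an estimated correlation), and their median was 3.16 with the cohort as a block and 2.83 in the first cohort. The unfolded protein response was higher in 12 of 13 members, by a median of 0.25 (adjusted p = 9.40e-05, and adjusted p = 0.374 with an estimated correlation). It contains Atf4, a stress-induced transcription factor, at 0.36 ± 0.15 (SE) and Sel1l, of the ER degradation machinery, at 0.36 ± 0.14. With the cohort as a block its median was 0.13 (adjusted p = 0.00230), within the first cohort 0.16. Plasma cell genes were higher in 4 of 4 members, by a median of 0.41 (adjusted p = 0.0314, and adjusted p = 0.635 with an estimated correlation), and the blocked median was 0.59 (adjusted p = 0.000832), the first-cohort median 0.72. With the block 3 plasma cell genes passed over the list alone, against 0 without it. With the acinar mean added to the cohort block, the plasma cell and unfolded protein response lists no longer passed (adjusted p = 0.0627 and 0.139), at medians of 0.43 and 0.10. Without wild-type replicate 2 the unfolded protein response median was 0.15 (adjusted p = 0.00312).

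Goblet cell genes were higher in 8 of 10 members, by a median of 0.23 (adjusted p = 0.0239, and adjusted p = 0.472 with an estimated correlation). The call ended with the cohort as a block (median 0.01, adjusted p = 0.287), within the first cohort (0.06, adjusted p = 0.247) and with the replicate number as a block (adjusted p = 0.248). Absorptive colonocyte genes were higher in 10 of 14 members, by a median of 0.12 (adjusted p = 0.0464, and adjusted p = 0.374 with an estimated correlation). Among them Ceacam1, an epithelial adhesion molecule, differed by 0.51 ± 0.23 (SE). That call also ended with the cohort block (0.11, adjusted p = 0.0815), within the first cohort (0.04, adjusted p = 0.232) and with the replicate number as a block (adjusted p = 0.108), and the list passed with the Osr2 level added to the cohort block (0.10, adjusted p = 0.0439). The goblet call ended without wild-type replicate 3 (adjusted p = 0.0555) or 4 (0.0963, median 0.36) or vehicle replicate 3 (0.0539). The plasma cell call ended without wild-type replicate 2 (adjusted p = 0.120), 3 (0.0626) or 4 (0.0586) or vehicle replicate 1 (0.0642), 2 (0.0891) or 3 (0.132). The colonocyte call ended in 11 of 24 cases, with an adjusted p of 0.0501 to 0.175: without wild-type replicate 2 or 3, vehicle replicate 1, 2, 3, 5 or 8, naproxen replicate 6, or ATB-346 replicate 1, 2 or 6. Its median was 0.04 without wild-type replicate 2 and 0.22 without wild-type replicate 4.

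Single genes with the smallest p in the genotype comparison were Ttc7, Pnliprp2, Heph, Jak2 and Tjp3 on the higher side. Heph, a ferroxidase that exports iron from enterocytes, differed by 0.32 ± 0.09 (SE), Jak2, a cytokine receptor kinase, by 0.19 ± 0.05, and the tight junction gene Tjp3 by 0.28 ± 0.08, each in 8 of 8 arrays. On the lower side stood Ptpdc1, Kcnn4, Zfp871, Prrc2b and Crispld2, where Kcnn4, a calcium-activated potassium channel, differed by -0.31 ± 0.08. Apc read 6.63 ± 0.13 in ApcMin and 6.70 ± 0.13 in wild type, and since Min is a point mutation this level checks no label. The Wnt target and stem cell list had 5 members higher and 5 lower (median 0.02, adjusted p = 0.781). Myc (6.09 ± 0.07 in ApcMin vehicle) and Ptgs2, the inducible cyclooxygenase (5.94 ± 0.05), lay near the floor of 5.65 in all groups and were not tested. Limma called 0 of 9048 genes (smallest adjusted p = 0.737), with 582 at an unadjusted p under 0.05 against 452.4 expected by chance, and 0 under every other setting run. In simulations from these arrays' residuals with 200 genes changed at once, 66.9% of those changed by 0.5 and 93.7% of those changed by 1 were recovered. This does not give the power to find a few changed genes, and the simulations left out the cohort. In list simulations of the same kind, 5.3 unchanged lists per run were called with the preset correlation, against the 5 called here. The simulated count was adjusted over 33 lists and the real one over 132 tests, so they are not like for like.

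The next comparison asked what 1 week of ATB-346 had left in ApcMin colon 7 weeks later. Gsdmc2, of the pore-forming gasdermin family, lay at 11.18 ± 0.23 (SD, n = 6) after ATB-346 and 12.21 ± 0.55 (n = 8) after vehicle, a difference of -1.03 ± 0.21 (SE). Gsdmc3 differed by -1.07 ± 0.24, in 5 of 6 arrays, and the near-identical Gsdmc paralogues may share probe signal. Ccnd1, which encodes cyclin D1 of the G1 phase, lay at 10.18 ± 0.24 against 10.59 ± 0.08 and below the vehicle mean in 6 of 6 arrays, by -0.41 ± 0.09. Capza1, of the actin capping protein, differed by -0.43 ± 0.09 and Ube2k, a ubiquitin-conjugating enzyme, by -0.21 ± 0.05. Higher after ATB-346 were Fnip1, a folliculin partner (0.31 ± 0.06), the lysosomal membrane gene Tmem192 (0.34 ± 0.07), Mcrs1 (0.24 ± 0.05), Lrrc40 (0.31 ± 0.07) and the Integrator subunit gene Ints7 (0.36 ± 0.08), each in 6 of 6 arrays.

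None of these 10 genes passed the adjustment over all genes (limma adjusted p = 0.135 for each): 0 of 9048 genes were called, with 632 at an unadjusted p under 0.05. Ccnd1 passed when adjusted over the Wnt target list alone (adjusted p = 0.000765). With the cohort as a block, limma called 28 genes, 17 higher and 11 lower. These included Fnip1 (0.32, adjusted p = 0.0348), Tmem192 (0.33, adjusted p = 0.0474), Mcrs1 (0.23, adjusted p = 0.0462), Lrrc40 (0.29, adjusted p = 0.0462), Capza1 (-0.44, adjusted p = 0.0426), Gsdmc2 (-1.03, adjusted p = 0.0426), Ccnd1 (-0.41, adjusted p = 0.0462) and Gsdmc3 (-1.15, adjusted p = 0.0410), but not Ints7 (adjusted p = 0.0555) or Ube2k (adjusted p = 0.0527). Within the first cohort alone 16 genes were called (14 higher, 2 lower), within the second alone 0, and with the series matrix values 1. The within-cohort differences were -0.32 and -0.57 for Ccnd1, -0.83 and -1.30 for Gsdmc2 and 0.34 and 0.29 for Fnip1. With the Osr2 level added to the cohort block 53 genes were called, and with the acinar mean added 1. Without vehicle replicate 1, Gsdmc2 passed (-1.14, adjusted p = 0.0500), and without ATB-346 replicate 4, Gsdmc3 did (-1.31, adjusted p = 0.0213).

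**Figure D2:**
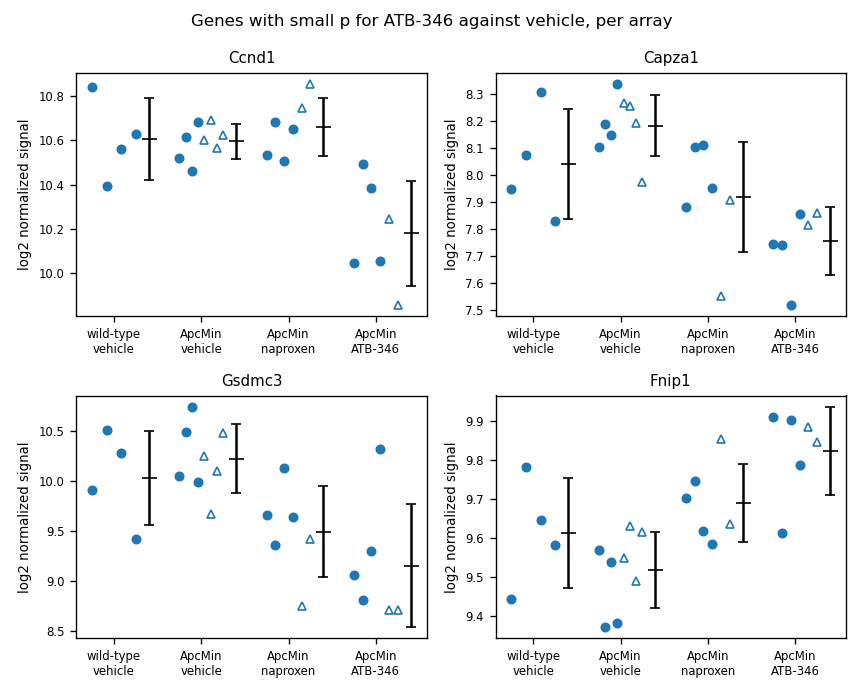
Log2 normalized signal (y axis) of Ccnd1, Capza1, Gsdmc3 and Fnip1 in each array of the 4 groups (x axis), with replicates 1 to 4 as filled circles, replicates 5 to 8 as open triangles and the mean ± SD as a bar. Ccnd1 lay between 9.86 and 10.49 in the ATB-346 arrays and between 10.46 and 10.69 in the vehicle arrays.

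In the ATB-346 comparison, 9 of 33 lists passed camera with the preset correlation, 1 upward and 8 downward, and 0 passed with an estimated correlation. Acinar genes were lower in 14 of 14 members, by a median of -3.09 (adjusted p = 1.93e-20, and adjusted p = 0.374 with an estimated correlation), and 13 passed when adjusted over the list alone, 0 over all genes. Their median was -3.14 with the cohort as a block and -2.90 and -3.28 within the cohorts. The acinar mean lay at 6.81 ± 0.08 after ATB-346 and 9.79 ± 2.79 after vehicle (exact permutation test, two-sided p = 0.0160, n = 6 and 8, adjusted over 8 tests 0.120). With the cohorts kept, the exact p was 0.0171 (adjusted 0.0686).

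Genes of MHC class II antigen presentation were lower in 10 of 10 members, by a median of -0.31 (adjusted p = 1.09e-06, and adjusted p = 0.447 with an estimated correlation). H2-Ab1, a class II chain, differed by -0.33 ± 0.14 (SE) and Ciita, the class II transactivator, by -0.35 ± 0.14, each lower in 6 of 6 arrays. The median was -0.36 with the cohort as a block and -0.52 and -0.15 within the cohorts (second cohort adjusted p = 0.0626). B cell and follicle genes were lower in 6 of 6 members (median -0.33, adjusted p = 0.00195, and adjusted p = 0.626 with an estimated correlation), with medians of -0.61 and -0.09 within the cohorts (second cohort adjusted p = 0.471). Vehicle replicates 1 and 2 had the highest means of both lists, and the ATB-346 arrays lay between 6.80 and 7.14 for B cell and between 8.44 and 8.86 for MHC class II genes. The B cell median was -0.20 without vehicle replicate 1 (adjusted p = 0.0379) and -0.22 without vehicle replicate 2 (0.0268). Cd79b, of the B cell receptor, differed by -0.55 ± 0.31. Macrophage genes were lower in 12 of 14 members (median -0.20, adjusted p = 0.000637, and adjusted p = 0.472 with an estimated correlation), among them the complement gene C1qa (-0.23 ± 0.09), and lay at -0.25 with the block and -0.15 and -0.19 within the cohorts. Oxidative phosphorylation was the list called upward, with 23 of 25 members higher by a median of 0.10 (adjusted p = 0.000637, and adjusted p = 0.522 with an estimated correlation), 0.11 with the block, 0.12 and 0.11 within the cohorts and 0.06 without ATB-346 replicate 5 (adjusted p = 0.0463). The oxidative phosphorylation mean also differed between the cohorts, at 11.79 to 11.86 in vehicle replicates 1 to 4 and 11.91 to 12.19 in replicates 5 to 8. In ATB-346 arrays it was 11.92 to 12.03 and 12.15 to 12.27. A leftover of the cohort shift was thus not separated from an ATB-346 effect on this list. No member of these 4 lists passed when adjusted over its list alone. With the cohort as a block, 8 of the 10 MHC class II genes, 6 oxidative phosphorylation genes, 1 macrophage gene and 0 B cell genes did, and over all genes Ndufb5, of respiratory complex I, passed (0.45, adjusted p = 0.00254), at 0.24 without the block (adjusted p = 0.995) and with a shift of 1.24 between the cohorts (adjusted p = 6.25e-13). With the acinar mean added to the cohort block, the macrophage and oxidative phosphorylation lists no longer passed (adjusted p = 0.0966 and 0.0923), at medians of -0.14 and 0.03.

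The other 4 lists called downward after ATB-346 lost their call with the cohort as a block. Unfolded protein response genes, lower in 12 of 13 members, had a median of -0.11 (adjusted p = 0.00623, and adjusted p = 0.522 with an estimated correlation) and -0.07 with the block (adjusted p = 0.0553), -0.11 and -0.07 within the cohorts, and passed with the Osr2 level added (-0.06, adjusted p = 0.0441). Fibroblast and matrix genes had a median of -0.10 (adjusted p = 0.0235, and adjusted p = 0.699 with an estimated correlation) and -0.07 with the block (adjusted p = 0.0894). Their within-cohort medians were 0.08 (adjusted p = 0.292) and -0.44 (adjusted p = 1.82e-09), and the collagen gene Col1a1 differed by -0.09 and -0.74. Goblet genes, lower in 8 of 10 members, had a median of -0.19 (adjusted p = 0.0314, and adjusted p = 0.498 with an estimated correlation) and -0.16 with the block (adjusted p = 0.239), -0.24 and -0.12 within the cohorts. Paneth cell and antimicrobial genes, lower in 5 of 7 members, had a median of -0.24 (adjusted p = 0.0441, and adjusted p = 0.374 with an estimated correlation) and -0.22 with the block (adjusted p = 0.107), -0.34 and -0.29 within the cohorts, and passed with the Osr2 level added (-0.50, adjusted p = 0.0104). The goblet call ended without vehicle replicate 5 (adjusted p = 0.0851) or 8 (0.125) or ATB-346 replicate 1 (0.110, median -0.09) or 4 (0.111), and the unfolded protein response call without ATB-346 replicate 4 (0.0705, median -0.05). The unfolded protein response median was -0.19 without vehicle replicate 1, -0.07 without vehicle replicate 8, and -0.20 and -0.19 without ATB-346 replicates 5 and 6. The fibroblast call ended without vehicle replicate 7 (adjusted p = 0.135) or 8 (0.0526) or ATB-346 replicate 1 (0.0678), 2 (0.0643) or 6 (0.134), and its median was -0.16 without vehicle replicate 4 and -0.19 and -0.15 without ATB-346 replicates 3 and 4. The Paneth call ended in 8 of 24 cases, with an adjusted p of 0.0508 to 0.0943: without wild-type replicate 3, vehicle replicate 6 or 7, naproxen replicate 6, or ATB-346 replicate 2, 3, 4 or 6. Its median was -0.42 and -0.39 without vehicle replicates 1 and 3 and -0.53 without ATB-346 replicate 1. The hydrogen sulfide genes Cbs (-0.10 ± 0.16), Cth (0.15 ± 0.14) and Mpst (0.10 ± 0.25) and the constitutive cyclooxygenase gene Ptgs1 (0.02 ± 0.20) did not pass. In simulations with 200 genes changed at once, 74.3% of those changed by 0.5 were recovered, which does not give the power for a few changed genes. In simulations that left out the cohort, 4.7 unchanged lists per run were called with the preset correlation, against the 9 called here. Adjustment was over 33 lists in the simulations and over 132 tests for the real count, so they are not like for like.

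The same question was asked of naproxen. Ang4, an antimicrobial angiogenin of the gut epithelium, lay at 9.52 ± 1.56 (SD, n = 6) after naproxen and 13.03 ± 1.73 (n = 8) after vehicle, a difference of -3.51 ± 0.90 (SE), lower in 6 of 6 arrays. Mptx1, a mucosal pentraxin, lay at 9.17 ± 2.07 against 12.84 ± 0.87, lower in 5 of 6 arrays. Higher after naproxen were Scg5, a chaperone of neuroendocrine cells (0.48 ± 0.10), Eef1a2, an elongation factor of neurons and muscle (0.34 ± 0.07), Minar2 (0.44 ± 0.10), the cilium gene Evc (0.27 ± 0.06) and Stmn2, a neuronal microtubule regulator (0.40 ± 0.09), each in 6 of 6 arrays. Also lower were the complement regulator Cr1l (-0.32 ± 0.08), the lipase gene Pnliprp2 (-2.32 ± 0.59) and Rab27b, of secretory granules (-0.28 ± 0.08). Over all genes limma called 0 of 9048 (smallest adjusted p = 0.394), with 790 at an unadjusted p under 0.05, and 0 under every other setting run, the cohort block included. In simulations with 200 genes changed at once, 75.2% of those changed by 0.5 were recovered, which does not give the power for a few changed genes.

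The transcription factor gene Osr2, chosen after its values were seen, lay at 12.10 ± 0.83 (n = 6) after naproxen and 9.43 ± 2.59 (n = 8) after vehicle (exact permutation test, two-sided p = 0.0380, adjusted over 8 tests 0.120). With the cohorts kept, the difference was 2.91 (exact p = 0.0400, adjusted 0.107). Of the posterior Hox and distal colon list, Hoxa13 at -0.41 and Hoxd10 at 1.21 passed when adjusted over the list alone (adjusted p = 0.0485 for each), and neither passed over all genes. Hoxa13 lay at 6.64 ± 0.33 after naproxen and 7.06 ± 0.37 after vehicle.

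**Figure D3:**
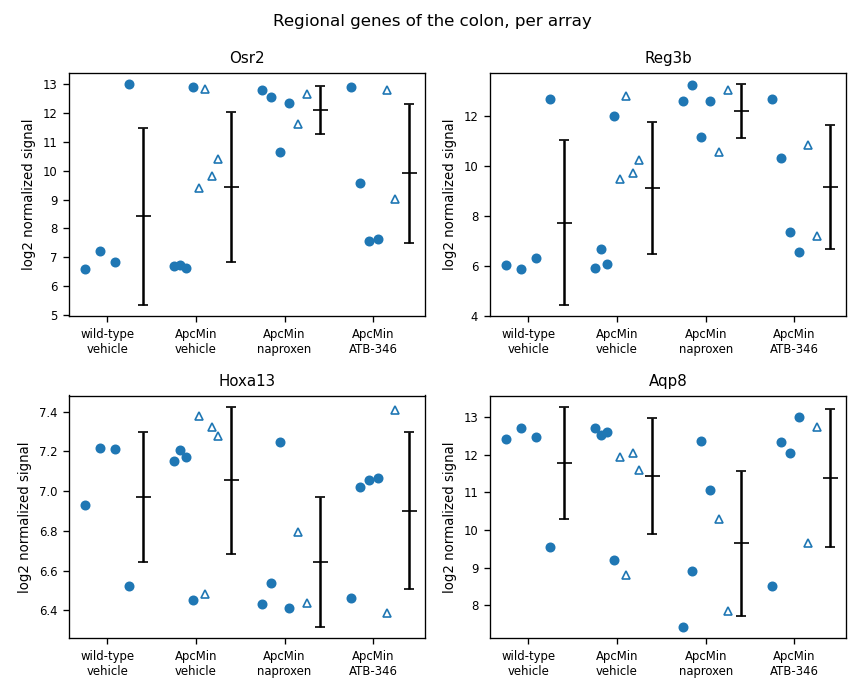
Log2 normalized signal (y axis) of Osr2, Reg3b, Hoxa13 and Aqp8 in each array of the 4 groups (x axis), with replicates 1 to 4 as filled circles, replicates 5 to 8 as open triangles and the mean ± SD as a bar. Arrays high in Osr2 and Reg3b tended to be low in Hoxa13 and Aqp8 (Reg3b and Aqp8 were also chosen after their values were seen); all 6 naproxen arrays had Osr2 above 10.6, while vehicle arrays ranged from 6.64 to 12.89.

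In the naproxen comparison, 8 of 33 lists passed camera with the preset correlation, 4 in each direction, and 0 with an estimated correlation. Enteric neuron and glia genes were higher in 6 of 6 members, by a median of 0.25 (adjusted p = 0.000317, and adjusted p = 0.374 with an estimated correlation), 0.27 with the cohort as a block and 0.24 and 0.36 within the cohorts. Stmn2 (adjusted p = 0.00183) and Tac1, which encodes substance P (0.32 ± 0.10, adjusted p = 0.0115), passed when adjusted over the list alone, and 6 members did with the block. A list gained with the block was smooth muscle (median 0.15, adjusted p = 0.0358, and adjusted p = 0.815 with an estimated correlation), at 0.11 without it (adjusted p = 0.103). Goblet cell genes were lower in 8 of 10 members, by a median of -0.33 (adjusted p = 0.00399, and adjusted p = 0.374 with an estimated correlation), and Ang4 (adjusted p = 0.00755) and Clca1 (-0.89 ± 0.31, adjusted p = 0.0410) passed over the list alone. The goblet median was -0.31 with the cohort as a block, where the call was lost (adjusted p = 0.0634), and -0.34 and -0.29 within the cohorts. Nrf2 target genes were higher in 10 of 13 members, by a median of 0.33 (adjusted p = 0.0171, and adjusted p = 0.699 with an estimated correlation). Hmox1, heme oxygenase 1, reached 7.64 ± 1.33 against 6.81 ± 0.17, with naproxen replicates 4 and 6 well above all other arrays. The Nrf2 median was 0.34 with the block and 0.21 and 0.26 within the cohorts, and the call ended without naproxen replicate 4 (median 0.22, adjusted p = 0.0892) or 6 (0.13, adjusted p = 0.321). With the Osr2 level added to the cohort block, the goblet call stayed lost (median -0.11, adjusted p = 0.133) and the Nrf2 call held (median 0.08, adjusted p = 0.0441).

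Acinar genes were lower after naproxen in 14 of 14 members, by a median of -2.07 (adjusted p = 1.11e-09, and adjusted p = 0.498 with an estimated correlation), with -2.13 under the cohort block and -1.31 and -3.23 within the cohorts and -1.38 without vehicle replicate 7, and 0 passed over the list alone. The acinar mean of 7.78 ± 1.41 differed from that of vehicle with an exact p of 0.121 (n = 6 and 8). B cell genes (median -0.39, adjusted p = 0.00585, and adjusted p = 0.679 with an estimated correlation) were lower in 6 of 6 members and MHC class II genes (-0.17, adjusted p = 0.00894, and adjusted p = 0.699 with an estimated correlation) in 10 of 10. With the block the medians were -0.44 and -0.20, and 4 B cell genes passed over the list alone, against 0 without it. Within the cohorts they were -0.66 and -0.02 for B cell genes and -0.45 and 0.10 for MHC class II genes, neither list called in the second cohort (adjusted p = 0.717 and 0.336). Without vehicle replicate 1, which with vehicle replicate 2 had the highest means of both lists, both calls ended (medians -0.26 and -0.10, adjusted p = 0.0642 and 0.117), and without naproxen replicate 4 the MHC call did (0.0732). With the Osr2 level added to the cohort block both calls ended (medians -0.14 and -0.12, adjusted p = 0.145 and 0.0781), as did that of oxidative phosphorylation (median 0.05, adjusted p = 0.411). Cell cycle genes, higher in 16 of 19 members (median 0.09, adjusted p = 0.0314, and adjusted p = 0.715 with an estimated correlation), included the mitotic kinase gene Aurka (0.40 ± 0.14), with medians of 0.08 under the block and 0.21 and 0.01 within the cohorts (second cohort adjusted p = 0.663). Oxidative phosphorylation genes were higher in 17 of 25 members (0.08, adjusted p = 0.0464, and adjusted p = 0.699 with an estimated correlation), with 0.10 under the block and 0.14 and 0.09 within the cohorts (second cohort adjusted p = 0.751). With the acinar mean added to the cohort block both calls ended (medians 0.01 and 0.05, adjusted p = 0.380 and 0.255). The cell cycle call ended without vehicle replicate 3 (adjusted p = 0.116) or 4 (0.137) or naproxen replicate 4 (0.582, median 0.02) or 6 (0.0579), and its median was 0.14 without vehicle replicate 5 and 0.17 without naproxen replicate 3. That of oxidative phosphorylation ended in 14 of 24 cases, with an adjusted p of 0.0501 to 0.153: without wild-type replicate 3 or 4, vehicle replicate 1, 2, 3, 4 or 7, naproxen replicate 4, 5 or 6, or ATB-346 replicate 1, 2, 3 or 6. Its median was 0.05 without vehicle replicate 7 and 0.03 without naproxen replicate 4. In simulations that left out the cohort, 4.8 unchanged lists per run were called with the preset correlation, against the 8 called here. These counts are not like for like either, with adjustment over 33 lists in the simulations and 132 tests for the real count.

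The drugs were then compared with each other, at 14.5 mg/kg of ATB-346 and 10 mg/kg of naproxen. Ccnd1 lay at 10.18 ± 0.24 after ATB-346 and 10.66 ± 0.13 after naproxen (n = 6 each), a difference of -0.48 (95% interval -0.67 to -0.29), lower in 6 of 6 arrays. Nfkbia, which encodes the NF-kappaB inhibitor, differed by 0.57 (0.29 to 0.84), Gadd45b, a stress response gene, by 0.36 (0.18 to 0.55), the sialyltransferase gene St3gal4 by 1.10 (0.52 to 1.68), Fbxl4 by 0.32 (0.18 to 0.45) and Ap4b1 by 0.23 (0.11 to 0.35). Besides Ccnd1, lower values after ATB-346 were read for the glial receptor gene Gpr37l1 at -0.29 (-0.45 to -0.13), Zfpm2 at -0.30 (-0.46 to -0.13), Hpcal4 at -0.24 (-0.38 to -0.10) and Kctd15 at -0.27 (-0.43 to -0.11). Limma called 0 of 9048 genes (smallest adjusted p = 0.252, for Ccnd1), with 586 at an unadjusted p under 0.05, and 0 with the cohort as a block. Without ATB-346 replicate 2, Ccnd1 was called (-0.54, adjusted p = 0.0320). Adjusted over their lists alone, Ccnd1 (adjusted p = 0.000278), Nfkbia (adjusted p = 0.00355), Socs3 (-0.22, adjusted p = 0.0399) and the cell cycle inhibitor gene Cdkn1a (0.44, adjusted p = 0.0447) passed.

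Between the drugs, 4 of 33 lists passed camera with the preset correlation, all lower after ATB-346, and 0 passed with an estimated correlation. Enteric neuron and glia genes were lower in 6 of 6 members, by a median of -0.28 (adjusted p = 0.000637, and adjusted p = 0.374 with an estimated correlation), -0.28 with the cohort as a block and -0.18 and -0.38 within the cohorts (first cohort adjusted p = 0.0955). Tac1 (-0.31 ± 0.11), Uchl1 (-0.29 ± 0.11) and Stmn2 (-0.26 ± 0.10) passed when adjusted over the list alone (adjusted p = 0.0331), and 4 members did with the block. T and NK cell genes (median -0.19), acinar genes (-0.96) and Nrf2 targets (-0.29) had an adjusted p of 0.0314, 0.0314 and 0.0387 (adjusted p = 0.699, 0.715 and 0.699 with an estimated correlation). All 3 calls were lost with the cohort as a block (adjusted p = 0.0777, 0.0553 and 0.0815), and their medians within the cohorts were -0.22 and -0.12, -1.45 and -0.06, and -0.25 and -0.19. With the Osr2 level added to the block, the medians of T and NK genes and Nrf2 targets were both -0.04 (adjusted p = 0.733 and 0.411), while acinar genes passed (-1.26, adjusted p = 0.00462). The T and NK call ended without naproxen replicate 1 (adjusted p = 0.152) or 6 (0.0893) or ATB-346 replicate 2 (0.0980), 3 (0.0880), 4 (0.0705) or 6 (0.0735). The acinar call ended without naproxen replicate 1 (median -0.39, adjusted p = 0.315) or 3 (0.102) or ATB-346 replicate 1 (0.0681), 2 (0.0643) or 3 (0.0599), and the Nrf2 call without naproxen replicate 4 (median -0.18, adjusted p = 0.173) or 6 (-0.12, adjusted p = 0.560) or ATB-346 replicate 1 (0.0501), 2 (0.0959), 3 (0.0999) or 4 (0.111). The T cell receptor gene Cd3g differed by -0.40 (-0.86 to 0.07) and Hmox1 by -0.89 (-1.66 to -0.12), where naproxen replicates 4 and 6 stood well above all other arrays. The acinar mean was lower after ATB-346 with an exact two-sided p of 0.0455 (n = 6 each, adjusted over 8 tests 0.120), and 0.0143 with the cohorts kept (adjusted 0.0686). The hydrogen sulfide-producing enzyme genes Cbs, Cth and Mpst differed by -0.41 (-0.76 to -0.07), 0.27 (-0.04 to 0.58) and -0.21 (-0.76 to 0.34), and did not pass. The differences of Ptgs1, Apc and Ctnnb1 had intervals of -0.36 to 0.53, -0.23 to 0.09 and -0.37 to 0.48, which leave room for unequal responses. In simulations with 200 genes changed at once, 70.6% of those changed by 0.5 were recovered, which does not give the power for a few changed genes. In simulations that left out the cohort, 5.1 unchanged lists per run were called, against the 4 called here. Again the simulated count was adjusted over 33 lists and the real one over 132 tests, so they are not like for like.

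**Figure D4:**
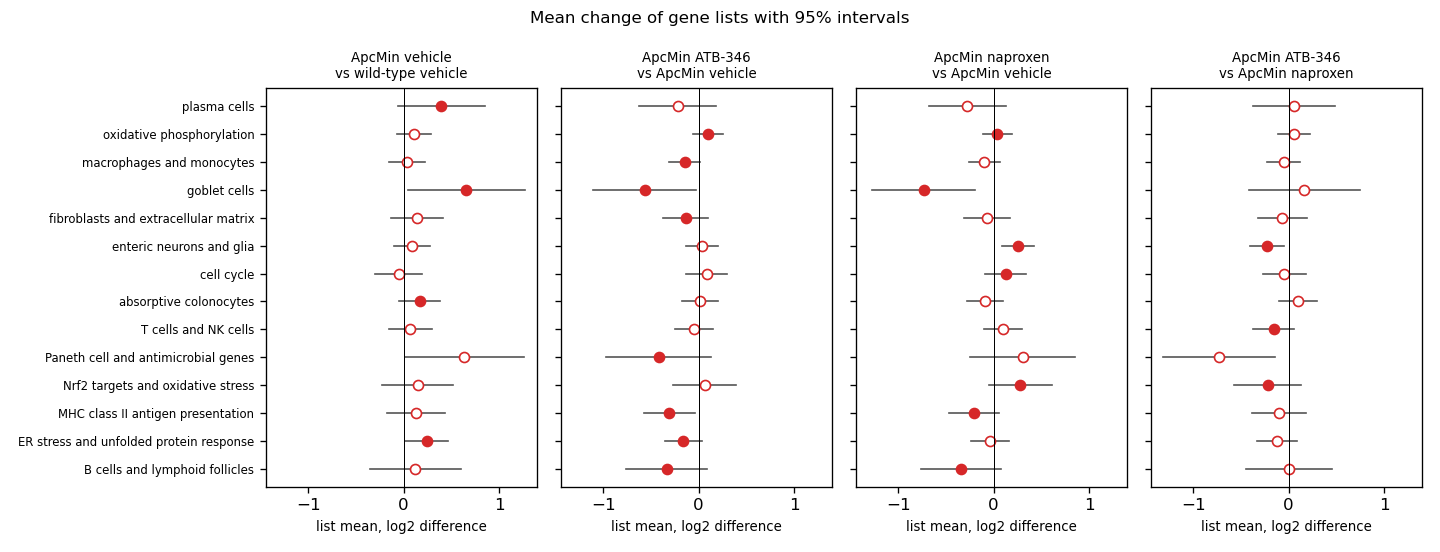
Mean log2 difference of the lists called in at least 1 comparison, the acinar list left out for scale (x axis, with 95% intervals as lines), for 14 gene lists (y axis) in the 4 comparisons. Filled circles passed camera with the preset correlation at an adjusted p under 0.05 and open circles did not; no list passed with an estimated correlation.

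Whether treated ApcMin colon moved towards wild type was asked across genes. With the 8 vehicle arrays split so that no array entered both changes, the genotype change and the ATB-346 change correlated across 9048 genes with r = -0.30 (SD 0.25 over 70 splits), and the naproxen change with r = -0.12 (SD 0.27). In simulations of unchanged groups, 36 of 100 and 60 of 100 lay as far from 0. Those simulations left out the cohort. With its shift kept, their means were -0.13 and -0.10, and 23 and 58 of 100 lay as far from 0. Measured from these means, 48 and 92 of 100 lay as far away as the observed values. Genes are not independent replicates. Without the split r was -0.58 for ATB-346 and -0.30 for naproxen, where shared controls alone gave -0.36 and -0.39, and the covariance differed from the simulated one by -0.0155 and -0.00281. The responses to both drugs correlated with r = 0.35 (SD 0.21), a value that 30 of 100 simulations equalled or exceeded in size (15 with the cohort shift kept), and with r = 0.65 without the split, against a simulated 0.44 (covariance difference 0.0183). Within the first cohort the 3 correlations were -0.23, -0.12 and 0.33, and 56, 74 and 37 of 100 simulations from that cohort alone lay as far from 0. Since limma called no gene in the genotype or drug comparisons, no called gene could be followed back, and the overlap of the drugs' calls was 0. Against wild type, limma called 0 of 9048 genes for ATB-346 (538 at an unadjusted p under 0.05) and 0 for naproxen (865). Without ATB-346 replicate 3, 1 gene was called between ATB-346 and wild type (adjusted p = 0.0454).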

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

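The tests of the acinar, regional and cohort-blocked patterns were chosen only after their results were seen, while the comparison of probe pairs between the cohorts and the counts over other splits of the arrays were set out before theirs. Ins2 and Osr2 were singled out after their values were seen. A single array was set apart when its gap to the nearest other array of its group, divided by the group's range, exceeded the 95% limit of Dixon's test. Chance marks about 1 in 20 groups in this way. Of 584 such tests 44 passed the limit, against 29.2 by chance.

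The first pattern is the difference of 3358 genes between arrays numbered 1 to 4 and 5 to 8, with the 28 genes called for ATB-346 once the cohort was a block. If transcript levels of the animals were the whole source, probes of 1 gene would share the shift, yet over 2298 genes with 2 probes they did so with r = 0.252, below the repeat correlation of the shift between vehicle and naproxen arrays (0.814) by 0.562 (95% interval 0.496 to 0.626), which argues against it. The same probe pairs shared the slope on Osr2 with r = 0.870, a difference of 0.618 (0.535 to 0.700), which a labelling or hybridization batch could produce. Both intervals come from 1000 resamples of genes taken as independent. They leave out the spread between arrays and so are too narrow for other samples. Of the 28 genes 82.1% changed in the direction of the cohort shift of the naproxen arrays, against 58.8% of all genes, and first-cohort ATB-346 arrays lay at 0.16 to 0.19 of the way to the second cohort, vehicle arrays at -0.19 to -0.06, so a leftover of the shift may account for part of them. However, 11 of the 28, Ccnd1, Capza1, Gsdmc2, Gsdmc3 and Fnip1 among them, were not called as different between cohorts, and an effect of ATB-346 stays open for these. The missing call does not show that a shift was absent. Among the 11, Gsdmc3 shifted by -0.45 (limma adjusted p = 0.0645) and Rbmx by 0.15 (0.0710), each in the direction of its ATB-346 change. After naproxen, Gsdmc2 (-0.64), Gsdmc3 (-0.73), Capza1 (-0.26) and Fnip1 (0.17) differed from vehicle in the same direction, none called, while Ccnd1 did not (0.07). The same vehicle arrays enter both drug changes. For these 4 genes a change particular to ATB-346 was not shown.

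The second pattern is the spread of acinar genes over vehicle arrays, from a list mean of 6.82 to 14.3. A candidate source is pancreatic tissue carried over into some samples: 96.2% of the variance of the 14 genes lay on 1 component, and in vehicle replicate 7, where all 14 exceeded 10, Ins2, of the pancreatic islet, read 9.82 against 5.86 to 5.96 in wild type (8.36 in naproxen replicate 1). Wild-type colon itself expresses 2 of the 14 (Cela1 at 12.22 and Clps at 10.36). Acinar means of the wild-type arrays lay between 6.75 and 7.27. ApcMin vehicle replicates 1 (6.82) and 6 (6.99), naproxen replicates 4 to 6 (6.76 to 6.96) and all ATB-346 arrays were no higher. The other ApcMin arrays were higher. These values argue against the genotype alone as the source. A part for the genotype stays open, as vehicle arrays differed from wild type with an exact permutation p of 0.0747 (n = 8 and 4, adjusted 0.120). An effect of ATB-346, whose arrays stayed between 6.72 and 6.94, was not separated from chance carry-over either.

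The third pattern is the spread of regional genes within groups, where Osr2 ran from 6.64 to 12.89 in vehicle arrays. The position along the colon that was sampled may be its source, but the posterior Hox genes of the list fixed in advance did not decide it, as they went both ways. With group and cohort means removed, Osr2 ran against Hoxa13 with r = -0.857 over 24 arrays (permutation p = 0.000160, adjusted over 3 relations 0.000480, Spearman's rho = -0.742 with permutation p = 0.000250, adjusted 0.000750, r = -0.849 without the 2 farthest arrays). It ran with Hoxd10 with r = 0.701 (permutation p = 0.00187, adjusted 0.00280, rho = 0.684 with permutation p = 0.00569, adjusted 0.00853, r = 0.655 without the 2 farthest arrays). A naproxen effect also stays open, as Osr2 was higher after naproxen within cohorts with an exact p of 0.04 (n = 6 and 8, adjusted 0.107), and position and naproxen are not separated where 6 of 6 naproxen arrays lie at the high end.

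Other splits of the same arrays, 100 per comparison with the real one included, did not exclude chance for the counts at an unadjusted p under 0.05 or for the lists. For the counts of called genes they decide nothing, since any split reaches a count of 0 (100 of 100 in each of the 6 comparisons). The highest other counts were 444 for the genotype, 475 for ATB-346, 1039 for naproxen, 8 between the drugs, and 1 each for ATB-346 and naproxen against wild type. At an unadjusted p under 0.05, 24 splits reached the 582 genes of the genotype comparison (highest other 2034), 23 the 632 of ATB-346 (2285), 21 the 790 of naproxen (2876) and 39 the 586 between the drugs (2020). For lists, 71 splits reached the 5 of the genotype comparison (highest other 12), 24 the 9 of ATB-346 (13), 31 the 8 of naproxen (13) and 76 the 4 between the drugs (12). The splits with 444, 475 and 1039 calls point to a structure of the samples. Which structure they follow was not tested. Those with 475 and 1039 calls put 5 of the 6 second-cohort arrays in the drug group, but the other splits that did so called 0 and 1 genes for ATB-346 and 0 and 0 for naproxen. At an unadjusted limma p under 0.05, all of these splits exceeded the real 632 and 790 genes. They reached 2164, 1741 and 1860 genes for ATB-346 and 2876, 2168 and 2019 for naproxen. A naproxen split with 4 second-cohort arrays in the drug group and an Osr2 difference of 2.62 reached 2403. That with 444 calls had 2 second-cohort arrays on each side and an Osr2 difference of -4.79, against 1.01 in the real split. With the cohort as a block, 2 of 100 splits within the cohorts, the real one included, gave at least the 28 genes of ATB-346 (highest other 69). By the rule set before these counts, under 5 in 100 splits, this result counts against chance. The block itself was chosen after the data were seen, among several settings, so the count does not exclude chance. Among the 16 genotype splits that part as many same-numbered pairs, 10 reached 582 genes (highest other 1007) and 11 reached 5 lists (highest other 8).

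Of the arrays set apart, naproxen replicate 4 and wild-type replicate 4 had 5 each, and naproxen replicate 1 and vehicle replicate 7 had 4 each. Wild-type replicate 4 was set apart by Klf4 (gap over range 0.886), Scg5 (0.903), Minar2 (0.899), Mptx1 (0.863) and Gsta4 (0.893), replicate 1 by Itln1 (0.913) and Lmod1 (0.843), replicate 2 by Cx3cr1 (0.928) and replicate 3 by Rab27b (0.942) and Fbxl4 (0.874). Vehicle replicate 7 was set apart by Mcrs1 (0.554), Col1a1 (0.580), Ndufb8 (0.545) and Atp5b (0.666), replicate 2 by Hspa1a (0.586) and Zfpm2 (0.570), replicate 4 by Tff3 (0.596) and Minar2 (0.580), and replicate 6 by Mptx1 (0.540) and Lmod1 (0.555). Naproxen replicate 4 was set apart by H2-Ab1 (0.654), Fcrla (0.629), Mzb1 (0.658), Ndufb8 (0.738) and Rrm2 (0.633), the last at 7.77 against 6.67 to 7.07 in the others. Naproxen replicate 1 was set apart by the pancreatic genes Pnliprp2 (0.719), Clps (0.706), Prss2 (0.763) and Ctrb1 (0.636), replicate 6 by Ttc7 (0.767), Hspa1a (0.727) and Itln1 (0.750), and replicate 3 by Pla2g2a (0.781). ATB-346 replicate 3 was set apart by Capza1 (0.650), Itln1 (0.686) and Atp5b (0.889), replicate 4 by Gsdmc3 (0.631), Pnliprp1 (0.782) and Tac1 (0.687), replicate 1 by Cela2a (0.802) and Scg5 (0.636), replicate 6 by Aif1 (0.676) and Atp5c1 (0.632), and replicate 2 by Ccl19 (0.630).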

How the results depend on the processing

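The cohort block, the fits within cohorts, the covariates and the cohort block without vehicle replicates 1 and 2 were chosen after the data were seen, the other alternatives before. Counts of called genes were 0 in each comparison, and stayed 0 under every setting run for the genotype, naproxen and naproxen-against-wild-type comparisons. For ATB-346 against vehicle they were 1 with the series matrix values, 6 with the replicate block (6 higher), 28 with the cohort block, 16 with only replicates 1 to 4, 53 with the cohort and Osr2 (30 higher, 23 lower) and 1 with the cohort and the acinar mean. Leaving out single arrays gave 0 to 1 for ATB-346 against vehicle (1 without vehicle replicate 1, adjusted p = 0.0500, or ATB-346 replicate 4, adjusted p = 0.0213), against naproxen (1 without ATB-346 replicate 2, adjusted p = 0.0320) and against wild type (1 without ATB-346 replicate 3, adjusted p = 0.0454), and 0 to 0 elsewhere.

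The lists called (5, 9, 8 and 4 for the genotype, ATB-346, naproxen and between the drugs) fell to 0 in each with an estimated correlation and with fry. With the cohort and Osr2 they were 9 for the genotype and 10 between the drugs. With the cohort and the acinar mean they were 1, 2, 4 and 1. With the cohort block they were 5 for ATB-346 and 1 between the drugs, and between the drugs 2 with only replicates 1 to 4 and 7 with only replicates 5 to 8. Single arrays left out gave 2 to 7 for the genotype (2 without wild-type replicate 3 or vehicle replicate 3, 3 without vehicle replicate 1), 7 to 11 for ATB-346, 5 to 11 for naproxen (5 without vehicle replicate 1 or naproxen replicate 6) and 2 to 6 between the drugs (2 without naproxen replicate 6, ATB-346 replicate 2 or ATB-346 replicate 3). Medians that reversed were those of fibroblast genes for ATB-346 in replicates 1 to 4 (0.0767), of MHC class II genes for naproxen in replicates 5 to 8 (0.10), and of acinar genes with their own mean as a covariate (0.0473 for ATB-346 and 0.0517 for naproxen), which removes them by construction. Without the filter on dim targets the genotype calls of goblet (adjusted p = 0.0771) and colonocyte genes (0.0834) ended, as did that of T and NK cell genes between the drugs (0.154, median -0.06). The series matrix values ended those of Paneth genes for ATB-346 (0.0502), oxidative phosphorylation for naproxen (0.0785) and, between the drugs, Nrf2 targets (0.0785) and acinar genes (0.0541). Median scaling ended that of oxidative phosphorylation for naproxen (0.385). For the other changes the cause was not tested.

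The replicate block, or pairing by number, left 5 list calls for ATB-346 and 2 between the drugs, and kept 17 of 26 list calls. For naproxen it ended that of cell cycle genes (median 0.05, adjusted p = 0.107). Outside the vehicle pairs, numbers were matched by no label and not every pair correlated above 0.1; own-numbered partners were not the best match throughout. For the genotype the block ended 2 list calls and gained 4, and for naproxen it gained smooth muscle (0.17, adjusted p = 0.00934) and adipocyte genes (0.75, adjusted p = 0.0370), each with an adjusted p of 0.787 with an estimated correlation. With the cohort block, the genotype medians of MHC class II and B cell genes reversed without vehicle replicates 1 and 2 (-0.0543 and -0.114). The correlation of the drug responses was 0.65 with all vehicle arrays in both changes. Single arrays left out gave 0.18 to 0.45 for it, -0.40 to -0.19 for the reversal by ATB-346 and -0.26 to 0.09 for that by naproxen. Of 712 values of named genes under the other alternatives set in advance 705 kept their direction and call, and of 2374 with an array left out 2333 did. No named gene was called in the main fit, so keeping the call meant staying uncalled. Most were picked for a small p in these same data, so a kept direction says little about stability. The number of genes tested was 9684 with the series matrix and 6032 with a stricter one. The chip as a block was not run because the files name no chips, nor sex as a covariate because all arrays read as male. Genes near the floor, such as Ptgs2 and Myc, are limited by signal over background.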

Other observations

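All genes in this part except list members were chosen after their values were seen, and no test was run on them. Hmox1, heme oxygenase 1, read 8.93 in naproxen replicate 4 and 9.72 in replicate 6, and 6.47 to 7.07 in the other 22 arrays. Gsta1, a glutathione transferase, read 13.18 and 13.28 in the same arrays and 8.77 to 11.72 in the others, and the quinone reductase gene Nqo1 9.63 and 9.26 against 7.62 to 8.84. Secreted antimicrobial genes varied among vehicle arrays: Itln1 (intelectin) read 10.27, 10.51, 10.49 and 10.37 in vehicle replicates 2, 3, 5 and 8 and 6.81 to 7.48 in the other 4, and Retnlb read 14.51, 14.79, 14.77 and 14.77 in the same 4 arrays. Insl5, a hormone of colonic enteroendocrine cells, ranged from 7.36 to 12.28 over the arrays, and Isx, an intestinal homeobox gene, from 6.34 to 11.54.

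Among lists that did not pass in any comparison without the cohort block, the smallest adjusted camera p was 0.0535 for enteroendocrine genes (naproxen, median 0.36, with Scgn at 0.46 passing over the list alone at 0.0249). It was 0.0613 for Wnt targets (between the drugs, -0.07) and for interferon-stimulated genes (ATB-346, -0.08), 0.0940 for adipocyte genes (naproxen, 0.61), 0.0989 for PPAR targets (ATB-346, 0.14) and for smooth muscle (genotype, 0.09), and 0.112 for xenobiotic metabolism (naproxen, 0.24). Hydrogen sulfide metabolism reached 0.119 (genotype, 0.10), apoptosis and p53 targets 0.122 (between the drugs, 0.03), ribosomal proteins 0.152 (genotype, -0.06), immediate early genes 0.162 (between the drugs, 0.19), endothelium 0.176 (genotype, -0.07) and tuft cells 0.219 (genotype, 0.13). Inflammatory genes reached 0.262 (genotype, 0.04), small-intestinal enterocytes 0.280 (naproxen, 0.13), hypoxia 0.376 (ATB-346, 0.08), prostanoid genes 0.385 (ATB-346, -0.03) and the circadian clock 0.499 (genotype, -0.02). With the cohort as a block, immediate early genes passed in the genotype comparison (0.15, adjusted p = 0.0176) and smooth muscle for naproxen (0.15, adjusted p = 0.0358), with an adjusted p of 0.804 and 0.815 with an estimated correlation. Acot1, a PPAR target, passed over its list alone for ATB-346 against vehicle (0.35, adjusted p = 0.0427), as did the adipocyte gene Acvr1c for ATB-346 against vehicle (0.25, adjusted p = 0.0106) and against naproxen (0.23, adjusted p = 0.0346), and Itln1 for naproxen against vehicle (-1.97, adjusted p = 0.0303). Of lists read by member, Hba-a1, a globin gene, lay between 9.91 ± 0.89 and 10.33 ± 1.43 over the 4 group means, Hbb-b1 between 6.94 ± 0.33 and 7.62 ± 1.16, ERAF between 6.50 ± 0.25 and 6.60 ± 0.22, and the mast cell gene Hdc between 6.46 ± 0.12 and 6.71 ± 0.20. No neutrophil gene lay above the filter.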
